A study of Vitis vinifera with 219 samples.

How the data were processed

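Berry pericarp of unthinned Vitis vinifera vines was sequenced through 3 seasons in 2 cultivars, Cabernet Sauvignon and Pinot noir. The study design gives 3 vine-row blocks per cultivar, and each sampling has 3 libraries. The 219 libraries form 73 groups of 3, each with 1 cultivar, 1 season and 1 time point. Per the labels' protocols, the libraries were non-directional, so transcripts of opposite strands cannot be separated.

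The deposited values are RPKM (reads per kilobase of gene model, scaled to the mapped reads) computed by the authors, with 1 column per library and 29971 gene IDs. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.6 and quantified with Cufflinks 2.0.2. The genome build, annotation release and options were not given in the sources used here, and no further scaling between libraries was stated. The column sums differ between libraries, so the values were not TPM. The table holds no read counts, so the depth of each library is unknown and no counting interval is given. Among 3142 genes whose highest RPKM was under 0.4, at most 7.61% of the ratios of their values to those of the first library fell in any 1 bin of 0.02 log2 (median over libraries 2.97%), so steps of whole reads were not seen.

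The table carries IDs without descriptions or symbols. Symbols of the 35 genes in 5 lists came from published use of these IDs, written down before the data were examined, and not from a file. None of the IDs in the table matched the reference table of symbols by ID (0 matches). Of the list symbols, 18 were found there, 17 on the chromosome number that the ID carries and 1 with an ID that carries no chromosome number, with 0 on another chromosome. The 5 lists were anthocyanin late steps (9 genes), flavonoid core steps (11), proanthocyanidin (8), stilbene (MYB14 and MYB15) and NAC factors named in ripening work (5). A further 19 lists, defined by words in descriptions, had no members and were not used here. MYBA1 and MYBA2, and CHS1 and CHS2, are close paralogs, and how reads shared between paralogs were assigned was not given.

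Values were transformed to log2(RPKM + 1). Genes with an RPKM of at least 1 in at least 3 libraries were tested, which left 21425 of the 27320 genes with a value above 0 in some library. The pseudocount makes changes of low genes smaller than the ratios of their RPKM. A model with a mean for each group was fitted to all 219 libraries (146 residual degrees of freedom) with limma 3.58.1 in R 4.3.3 (trend and robust options of eBayes), after reading with the data.table package (version 1.17.8). Each comparison was an equally weighted mean over cultivar-seasons, seasons or cultivar-days. Its standard error (SE) and p-value came from the spread of libraries within groups. They do not measure how far the change differed between cultivar-seasons, seasons or cultivar-days. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested and an absolute log2 change of at least 1.

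Windows were set from the labelled day after veraison, the start of colouring and softening. They were before onset (day -18 to -13), onset (day -9 to -6), veraison (day 0), post-veraison (day 7 to 11), day 21 (21 to 22) and day 42 (42 to 43). Each window held 1 time point of 3 libraries in each of the 6 cultivar-seasons. Comparisons followed ripening and its steps, cultivars at 3 stages, seasons at days 21 and 42 in both cultivars, and the cultivar difference of 3 steps as interaction terms. Each successive step within a cultivar-season was also tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over 70 tests of 5 lists in 14 comparisons, and again with an estimated correlation. The order of lists was read from the first sampling after the before-onset one at which a list's median log2 change reached 1 in size.

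Genes were named by a rule fixed before the data were examined. It took, per list, up to 4 members with the largest change past the threshold, and always MYBA1, MYBA2, UFGT, AOMT, 3AT and GST4, and allowed some to be left out for length. Genes known by ID alone were limited to 2 higher and 2 lower per comparison, among those with the same sign in every stratum and a mean RPKM of at least 5. List members named beyond the rule were chosen after their values were seen and are marked so. Under the alternatives, values were computed for every list member past the threshold.

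The alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean RPKM of at least 5 (13026 genes), quantile normalization, TMM scale factors, a replicate block, each replicate number left out, limma's treat test against a log2 change of 0.5, 2014 moved 1 time point later to match sugar content (re-anchored), each season left out, a fit of the compared libraries only, and stratum means as replicates. Re-anchoring did not match sugar content at every window. At the onset window of Pinot noir it was 1.11 g/100 ml in 2014 re-anchored and 1.34 by labelled day. In 2012 and 2013 it was 3.58 and 2.97 there. A further 4 were chosen after the data were seen: without 4 libraries that carried the other cultivar's marker genes, same-batch comparisons, both together, and without the genes that separated the batches. No library was left out of the reported comparisons. The test was tested on simulated data with 200 changed genes among 21425. In the 14 comparisons it recovered 97.0% to 100.0% of changes of 1.5 on the log2 scale and 98.5% to 100.0% of changes of 3, with at most 3 false calls. The simulated noise was normal and independent, with the fitted spread of each gene. Changes were the same in every season and were set in genes above a set mean level. The simulation therefore checks the computation and does not cover differences between seasons or low genes.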

Results

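Transcript levels in berry pericarp, with seeds removed, were compared in Cabernet Sauvignon and Pinot noir over 3 seasons. Cabernet Sauvignon had 39 libraries in 2012 (13 time points), 42 in 2013 (14) and 39 in 2014 (13). Pinot noir had 30 libraries in 2012 (10 time points), 33 in 2013 (11) and 36 in 2014 (12). Labelled days after veraison ran from -37 to 80 in Cabernet Sauvignon and from -36 to 53 in Pinot noir, with 3 libraries at each time point. The sum of RPKM per library ranged from 807469 to 1192350 (median 951780), and 20462 to 23465 genes had a value above 0. The read depth behind the values is unknown. Replicates of a group correlated at 0.952 or more. The first principal component held 48.2% of the variance and followed the labelled day, and the second held 12.7%. Mean sugar content at labelled day 0 was 6.83 and 7.84 g/100 ml in Cabernet Sauvignon of 2012 and 2013 and 8.47 and 9.23 in Pinot noir, against 2.26 and 1.11 in the 2014 samplings of these cultivars.

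**Figure D1:**
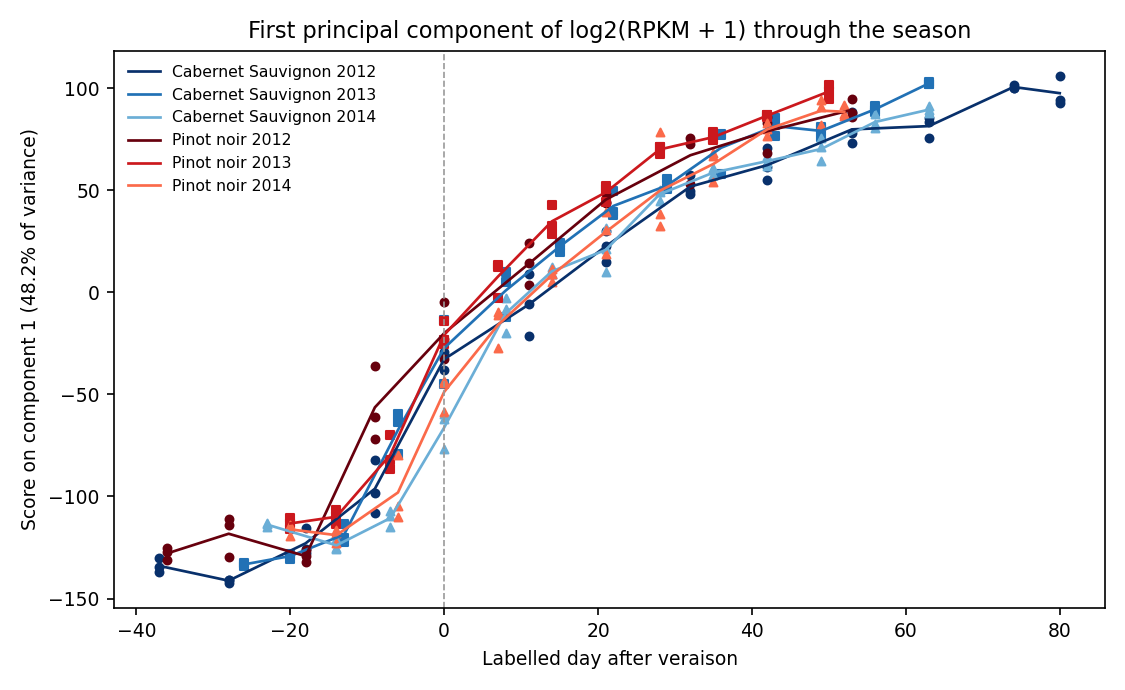
Score of each library on the first principal component of log2(RPKM + 1) against the labelled day after veraison, with lines through the means of 3 libraries in each cultivar and season. Scores were higher at the last than at the first sampling in all 6 cultivar-seasons, and at day 0 the 2014 samplings had lower means than those of 2012 and 2013.

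The main comparison asked which transcripts separate ripening berries at day 21 from green berries before onset, as a mean over the 6 cultivar-seasons (18 libraries per side). GST4 (VIT_04s0079g00690), a glutathione S-transferase of anthocyanin transport, was listed at 0 to 1.22 RPKM before onset and had a mean of 804 ± 208 RPKM (SD, n = 18) at day 21 (log2 change 9.41, SE 0.24). The colour-locus regulators MYBA2 (VIT_02s0033g00390) and MYBA1 (VIT_02s0033g00410) rose by 6.35 (SE 0.18) and 4.85 (SE 0.16) to 86.3 ± 28.1 and 32.3 ± 15.0 RPKM. UFGT (VIT_16s0039g02230), the glucosyltransferase that completes anthocyanins, rose by 5.63 (SE 0.16) to 51.2 ± 14.5 RPKM, and AOMT (VIT_01s0010g03510), which methylates them, by 4.63 (SE 0.18), from 1.92 to 60.7 RPKM. The acyltransferase 3AT (VIT_03s0017g00870) rose by 2.78 (SE 0.10). VIT_16s0050g00910 rose by 5.27 (SE 0.17), whereas its neighbour VIT_16s0050g00900, named after its value was seen, changed by -1.58 (SE 0.06; -0.79, under the size threshold, with a pseudocount of 5). Of the 9 anthocyanin genes, 8 rose and 1 fell, and the same counts held when adjusted over the list alone (camera adjusted p = 2.16e-07; adjusted p = 0.113 with an estimated correlation).

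Among the 11 flavonoid core genes, 6 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone. The chalcone synthase CHS3 (VIT_05s0136g00260) rose from 55.1 to 525 RPKM (log2 change 3.58, SE 0.18). The chalcone isomerase CHI (VIT_13s0067g03820) rose by 2.20 (SE 0.12) and CHS2 (VIT_14s0068g00920) by 1.93 (SE 0.15), while the flavonol regulator MYBF1 (VIT_07s0005g01210) changed by -1.99 (SE 0.08). For this list camera gave an adjusted p = 0.00195, and adjusted p = 0.406 with an estimated correlation. Of the 8 proanthocyanidin genes, 0 rose, 5 fell and 3 did not pass, also when adjusted over the list alone (camera adjusted p = 0.299). The anthocyanidin reductase ANR (VIT_00s0361g00040) went from 15.5 to 1.23 RPKM (log2 change -2.76, SE 0.14). MYBPAR (VIT_11s0016g01300) changed by -2.10 (SE 0.06; -0.78 with a pseudocount of 5), LAR2 (VIT_17s0000g04150) by -1.77 (SE 0.16) and MYB5a (VIT_08s0007g07230) by -1.55 (SE 0.06). LAR1 (VIT_01s0011g02960), named after its value was seen, changed by -1.11, and by -0.72 and -0.94 with quantile and TMM scaling and -0.46 with a pseudocount of 5, all under the size threshold. Of the 2 stilbene regulators, MYB15 (VIT_05s0049g01020) rose by 2.49 (SE 0.11) and MYB14 did not pass (camera adjusted p = 0.3).

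Of the 5 NAC factors, 4 rose and 1 did not pass, also when adjusted over the list alone (camera adjusted p = 6.31e-05; adjusted p = 0.0222 with an estimated correlation). NAC13 (VIT_02s0012g01040) rose from 3.19 to 63.6 RPKM (log2 change 4.00, SE 0.09), NAC11 (VIT_14s0108g01070) by 3.11 (SE 0.09), NAC33 (VIT_19s0027g00230) by 1.79 (SE 0.10) and NAC60 (VIT_08s0007g07670) by 1.67 (SE 0.10). The largest changes among genes known by ID alone were 10.76 for VIT_05s0094g00340 and 10.37 for VIT_11s0016g04920, and -8.42 for VIT_02s0154g00320 and -7.50 for VIT_03s0063g02360. In all, limma called 5262 genes, 1205 higher and 4057 lower, and 4869 had the same sign in all 6 cultivar-seasons. Of the 35 list genes 3 differed in their change between 2014 and the mean of 2012 and 2013 (interaction term), with -0.63 and -2.34 for LAR2 (VIT_17s0000g04150), -1.03 and -2.48 for MYBF1 (VIT_07s0005g01210) and -1.38 and -2.46 for MYBPAR (VIT_11s0016g01300), and with 2014 re-anchored by sugar these 3 did not and 6 others did, all with a smaller change in 2014. The median change of all genes was -0.28. Quantile scaling moved that median to 0.06 and the counts to 2084 higher and 2530 lower, and TMM scaling moved them to 0.01, 2008 and 2755. The size of the surplus of lower genes therefore depended on the scaling of RPKM.

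**Figure D2:**
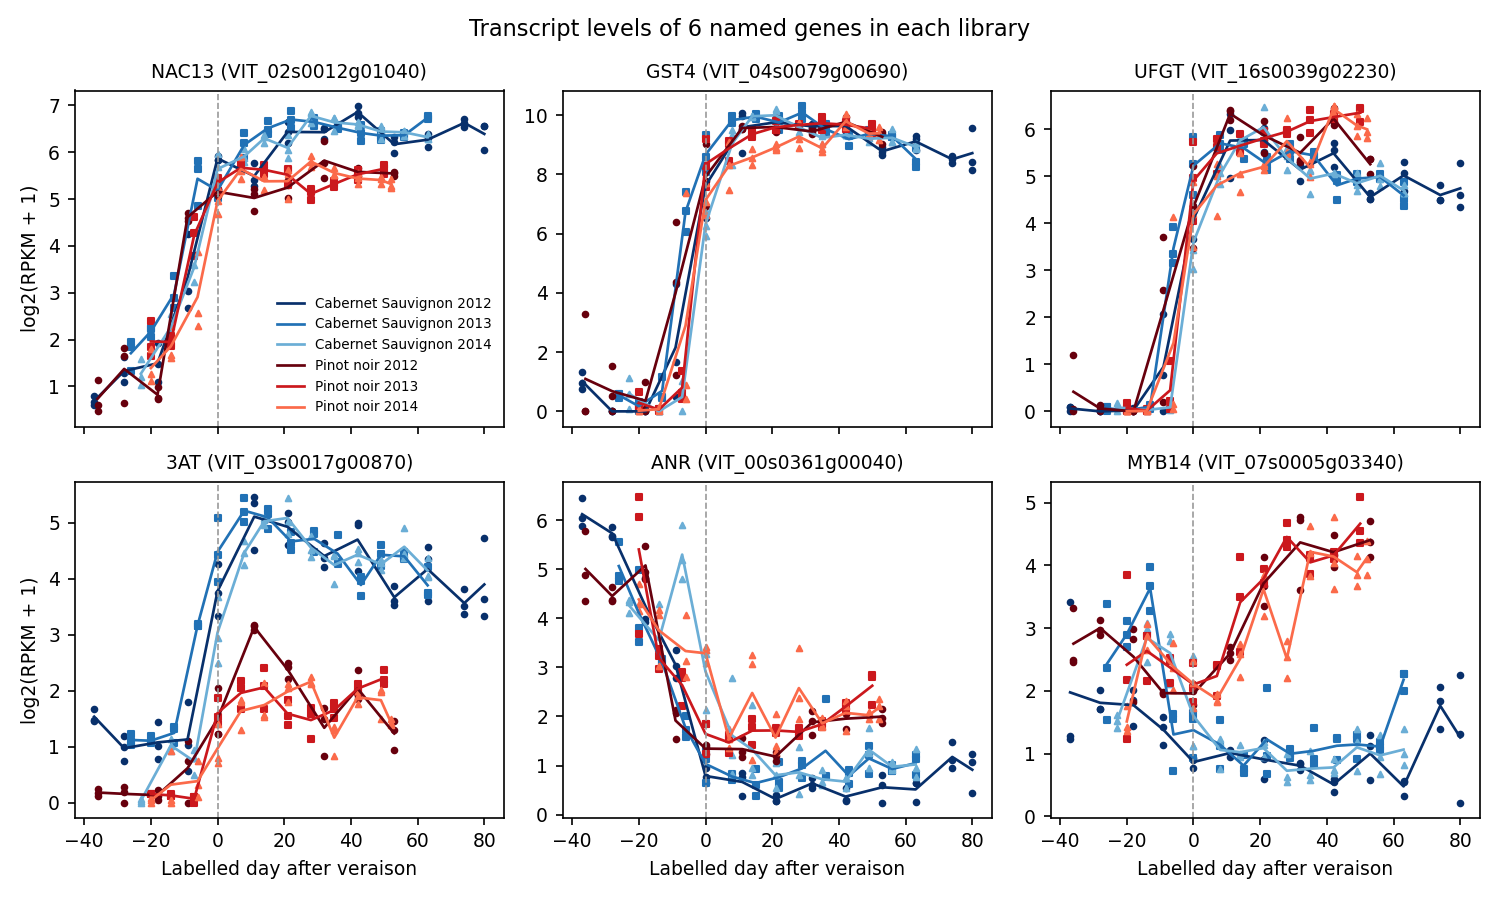
Transcript level, as log2(RPKM + 1), of NAC13, GST4, UFGT, 3AT, ANR and MYB14 in each library against the labelled day after veraison, with lines through the means of 3 libraries in each cultivar and season. NAC13, GST4, UFGT and 3AT were higher at day 21 than before onset, ANR was lower, and 3AT stayed higher and MYB14 lower in Cabernet Sauvignon than in Pinot noir at days 21 and 42.

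The onset step asked what changes before the labelled veraison (day -9 to -6 against before onset, 18 libraries per side). NAC13 (VIT_02s0012g01040) rose by 2.11 (SE 0.09), from 3.19 to 19.1 RPKM. NAC11 (VIT_14s0108g01070) rose by 1.34 (SE 0.09), NAC60 (VIT_08s0007g07670) by 1.26 (SE 0.10) and NAC33 (VIT_19s0027g00230) by 1.11 (SE 0.10). GST4 (VIT_04s0079g00690) rose by 2.65 (SE 0.24), MYBA2 (VIT_02s0033g00390) by 2.01 (SE 0.18), MYBA1 (VIT_02s0033g00410) by 1.75 (SE 0.16), UFGT (VIT_16s0039g02230) by 1.40 (SE 0.16) and VIT_16s0050g00910 by 1.21 (SE 0.17). With a pseudocount of 5, which narrows changes of low genes, values under the size threshold were 0.98 for MYBA2, 0.80 for MYBA1, 0.61 for UFGT, 0.93 for VIT_16s0050g00910, and 0.65 for both NAC11 and NAC33. NAC60 was at 0.77 without 2012. Of the NAC factors, 4 rose and 1 did not pass (camera adjusted p = 1.46e-08; adjusted p = 0.000703 with an estimated correlation). Of the anthocyanin genes, 5 rose and 4 did not pass (camera adjusted p = 0.000105; adjusted p = 0.33 with an estimated correlation). The 11 flavonoid core, 8 proanthocyanidin and 2 stilbene genes did not pass, and all these counts were the same adjusted over the list alone. These means hid a difference between seasons, as the onset step differed between 2014 and the mean of 2012 and 2013 in 17 of the 35 list genes (interaction term, 10 higher and 7 lower in 2014). With 2014 re-anchored by sugar 8 differed, 8 higher and 0 lower, of which 3 were among the 17 in the same direction and 3 in the opposite one. By labelled day the log2 changes in 2014 and in the other seasons were 0.47 and 1.78 for NAC11, 0.41 and 1.68 for NAC60, 1.17 and 2.59 for NAC13, 0.46 and 2.40 for MYBA1, 0.83 and 2.60 for MYBA2 and 1.65 and 3.14 for GST4. None of these 6 was lower past the threshold re-anchored, where MYBA2 and GST4 were higher in 2014. For NAC33 they were 0.51 and 1.42, a difference that did not pass. Among genes named after their values were seen they were opposite, with 0.66 and -1.56 for ANR (VIT_00s0361g00040), 0.58 and -1.41 for LAR2 (VIT_17s0000g04150), 0.20 and -1.41 for MYBPAR (VIT_11s0016g01300) and 1.25 and -0.64 for CHS3 (VIT_05s0136g00260), of which LAR2 and CHS3 also differed re-anchored. AOMT (VIT_01s0010g03510) did not pass at 0.99 (SE 0.18), and reached 1.07, past the threshold, without 4 libraries that carried the other cultivar's markers. The test called 619 genes, 290 higher and 329 lower, with 327 to 2871 per cultivar-season. This count fell without 2012, and rose without 2014 or with 2014 re-anchored. Over the alternatives it reached 1284 and the share higher reached 59.3%, so the small surplus of lower genes was not kept in all of them. With the 6 cultivar-season means as replicates, limma called 0 genes, with 5821 at an unadjusted p under 0.05.

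At the veraison step (day 0 against day -9 to -6), GST4 (VIT_04s0079g00690) rose by 4.82 (SE 0.24), from 35.2 to 255 RPKM. MYBA2 (VIT_02s0033g00390) rose by 3.11, AOMT (VIT_01s0010g03510) by 3.04, UFGT (VIT_16s0039g02230) by 2.97, VIT_16s0050g00910 by 2.88, MYBA1 (VIT_02s0033g00410) by 2.49 and 3AT (VIT_03s0017g00870) by 1.54 (0.77, under the size threshold, with a pseudocount of 5). CHS3 (VIT_05s0136g00260) rose by 2.38 (SE 0.18), CHI (VIT_13s0067g03820) by 1.03 (SE 0.12; 0.79, under the size threshold, without 2013) and NAC13 (VIT_02s0012g01040) by 1.35 (SE 0.09; 0.82 with 2014 re-anchored by sugar). ANR (VIT_00s0361g00040) changed by -1.17 (SE 0.14), and by -0.96 with quantile scaling and -0.68 with a pseudocount of 5, under the size threshold. The anthocyanin list had 7 higher and 2 not passed (camera adjusted p = 8.45e-13; adjusted p = 0.0222 with an estimated correlation), and the NAC list 1 higher and 4 not passed (adjusted p = 5.84e-05 and 0.0222). The flavonoid core list had 2 higher and 9 not passed (adjusted p = 0.000987; adjusted p = 0.372 with an estimated correlation). The proanthocyanidin list had 1 lower and 7 not passed, and the 2 stilbene genes did not pass. The step differed between 2014 and the other seasons in 7 of the 35 list genes (2 higher and 5 lower in 2014), with changes of 1.22 and 2.96 for CHS3, 0.27 and 1.40 for CHI and 2.07 and 0.99 for NAC13. Re-anchored 8 differed, 0 higher and 8 lower, and of the 7 only CHS3 was among them. It called 895 genes, 308 higher and 587 lower, against 396 and 403 with quantile scaling and 387 and 403 with TMM scaling.

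At the post-veraison step (day 7 to 11 against day 0), GST4 (VIT_04s0079g00690) rose by 1.53 (SE 0.24), UFGT (VIT_16s0039g02230) by 1.13 (SE 0.16), VIT_16s0050g00910 by 1.10 (SE 0.17) and 3AT (VIT_03s0017g00870) by 1.03 (SE 0.10). The last 3 fell under the size threshold in some alternatives: UFGT at 0.78 without 2012, VIT_16s0050g00910 at 0.82 with 2014 re-anchored and 3AT at 0.69 with a pseudocount of 5. The anthocyanin list had 4 higher and 5 not passed (camera adjusted p = 3.03e-08; adjusted p = 0.108 with an estimated correlation). None of the 11 flavonoid core genes passed, while camera gave an adjusted p = 2.26e-05 for a rise of the list (median log2 change 0.32), and adjusted p = 0.182 with an estimated correlation. The step called 225 genes, 71 higher and 154 lower, against 104 and 93 with quantile scaling and 111 and 94 with TMM scaling. Over all alternatives the count ranged from 79 to 775, and it also moved with a replicate number or with 2013 left out. From day 21 to day 42, MYBF1 (VIT_07s0005g01210) changed by -1.18 (SE 0.08; -0.38 with a pseudocount of 5) and was the 1 list gene of 35 past the threshold. That late step called 914 genes, 203 higher and 711 lower. In Cabernet Sauvignon of 2013 it crossed between the batches set out below, with 237 genes higher and 1183 lower in that cultivar-season. There the crossing from day 36 to day 43 alone had 4 higher and 382 lower. In both steps the remaining lists had no member past the threshold, and the counts adjusted over each list alone were the same at all 4 steps.

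The order of lists addressed which group of genes moved first. The NAC list's median reached a change of 1 no later than that of the anthocyanin list in 6 of 6 cultivar-seasons. It did so a sampling earlier in 2 of them, at day -9 against day 0 in Cabernet Sauvignon of 2012 and at day -7 against day 0 in Pinot noir of 2013. The NAC list's median change there was 1.23 and 1.02, the latter close to the cut-off of 1, and no test was made. The pseudocount also narrows early rises of low genes. In the other 4 both lists moved at the same sampling, so the sampling interval did not separate them. Sugar content at the NAC list's first sampling ranged from 1.11 to 3.58 g/100 ml.

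A further question was where in the season the transcriptome shifted most between successive samplings. In Cabernet Sauvignon of 2012 the largest step was from day -9 to day 0, with 2514 genes (702 higher and 1812 lower), while sugar content went from 1.55 to 6.83 g/100 ml. The surplus of lower genes at this step shrank with TMM scaling. With quantile scaling another step, from day -37 to day -28, was the largest with 2241 genes. In Cabernet Sauvignon of 2013 the largest step was from day -13 to day -6, with 1916 genes. There a library of day -13 lay in the other batch, as set out below. With a replicate number left out, the step from day -6 to day 0 could be the largest instead. In Pinot noir the largest step was from day -18 to day -9 in 2012 (2871 genes), from day -7 to day 0 in 2013 (1520) and from day -6 to day 0 in 2014 (1071). In Pinot noir of 2014 the step from day -20 to day -14 could be the largest with a replicate number left out. A library of that day -14 carried the marker genes of Cabernet Sauvignon. In Cabernet Sauvignon of 2014 the largest step was from day -23 to day -14 with 2259 genes, but the 3 libraries of day -23 carried the marker genes of Pinot noir. Without them the largest step of that season was from day 0 to day 8, with 1790 genes.

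**Figure D3:**
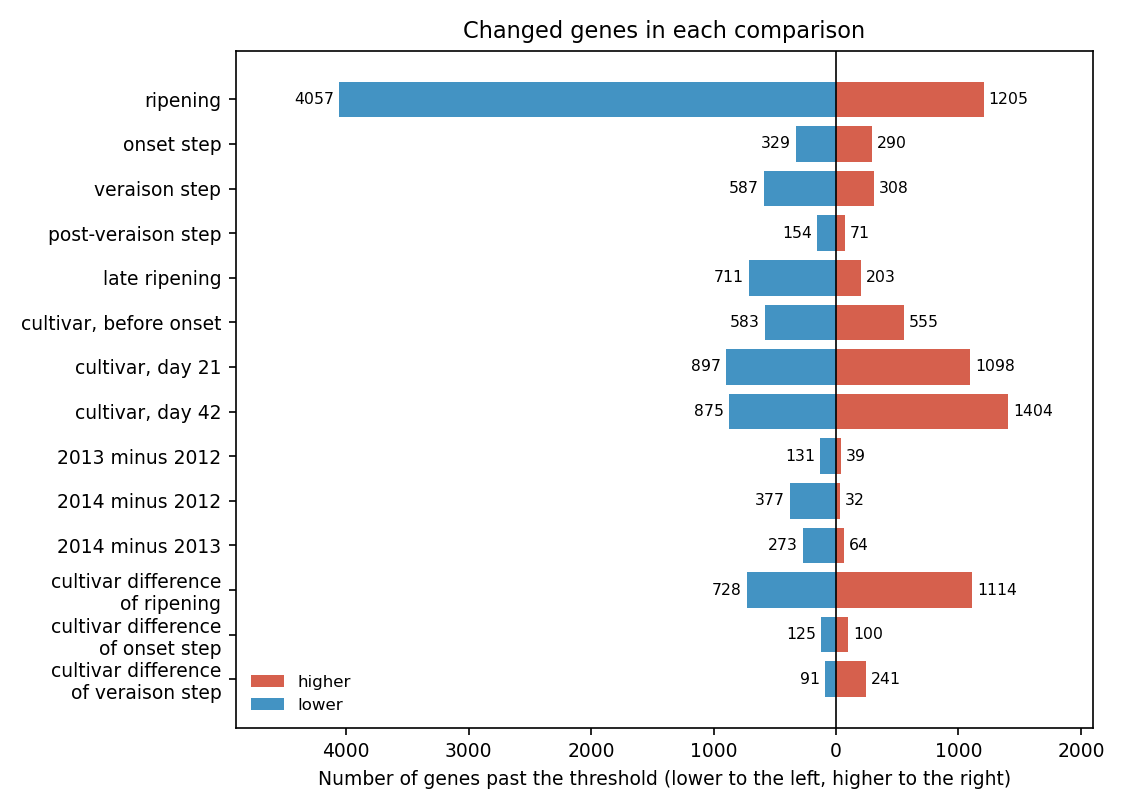
Number of genes past the threshold in each of the 14 comparisons, with genes higher to the right and genes lower to the left of 0. Ripening called 1205 higher and 4057 lower, a split that moved to 2084 and 2530 with quantile scaling.

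The cultivars were compared at 3 stages (Pinot noir minus Cabernet Sauvignon, mean over 3 seasons, 9 libraries per side). Cultivar goes together with rootstock, vine age and place in the vineyard in the labels' growth protocol, and these cannot be told apart. Mean sugar content before onset was 0.45, 0.48 and 0.43 in Cabernet Sauvignon of 2012 to 2014 and 1.23, 1.17 and 0.81 in Pinot noir. At day 21 it was 16.0, 17.8 and 15.2 against 16.2, 17.7 and 14.4. At day 42 it was 19.5, 23.8 and 20.9 against 26.5, 22.9 and 23.9. The same labelled day therefore need not be the same ripening stage, and stage was not separated from cultivar. Before onset, the leucoanthocyanidin dioxygenase LDOX (VIT_02s0025g04720) was higher in Pinot noir by 1.58 (SE 0.15; 80.7 against 25.1 RPKM), CHS3 (VIT_05s0136g00260) by 1.13 (SE 0.25) and CHS1 (VIT_14s0068g00930) by 1.09 (SE 0.19). These differences of CHS3 and CHS1 held in 15 of 21 alternatives each, and with 2014 re-anchored by sugar they were 0.66 and 0.62, under the size threshold. The leucoanthocyanidin reductase LAR1 (VIT_01s0011g02960) differed by -1.88 (SE 0.13; -0.79 with a pseudocount of 5), AOMT (VIT_01s0010g03510) by -1.52 (SE 0.25; -0.58 with a pseudocount of 5) and the flavanone hydroxylase F3H2 (VIT_18s0001g14310) by -1.01 (SE 0.11; -0.97 with the replicate block; held in 15 of 21 alternatives). The anthocyanin list had 1 higher, 1 lower and 7 not passed, the flavonoid core list 2, 1 and 8, and the proanthocyanidin list 0, 1 and 7, while the stilbene and NAC lists had none past the threshold. The test called 1138 genes, 555 higher and 583 lower. A Pinot noir library of 2014 at day -14 carried the marker genes of Cabernet Sauvignon, and without the 4 libraries of this kind the count was 1403 and 3AT (VIT_03s0017g00870) passed at -1.02 (-0.92 with them). With the 3 season means as replicates, limma called 0 genes, with 4930 at an unadjusted p under 0.05.

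At day 21, 3AT (VIT_03s0017g00870) was at 3.07 ± 1.04 RPKM in Pinot noir and 29.3 ± 6.52 in Cabernet Sauvignon (SD, n = 9; log2 difference -2.91, SE 0.14). MYB14 (VIT_07s0005g03340), a regulator of stilbene synthases, was at 12.3 ± 2.52 against 1.2 ± 0.78 RPKM (2.63, SE 0.19), and MYB15 (VIT_05s0049g01020) at 66.8 against 20.8 RPKM (1.72, SE 0.16). NAC11 (VIT_14s0108g01070) differed by -1.75 (SE 0.13; 9.30 against 34.5 RPKM). NAC13 (VIT_02s0012g01040) differed by -1.03 (-0.91 and -0.93 with quantile and TMM scaling) and F3H1 (VIT_04s0023g03370) by -1.05 (-0.93 and -0.95, -0.94 with the replicate block, -0.59 re-anchored), so these calls depend on the scaling. VIT_16s0050g00900 was higher by 1.04 (SE 0.09; 0.39 with a pseudocount of 5). Both stilbene genes were higher (camera adjusted p = 0.00882; adjusted p = 0.108 with an estimated correlation). The anthocyanin list had 1 higher, 1 lower and 7 not passed, the flavonoid core list 0, 1 and 10, the proanthocyanidin list 0, 0 and 8, and the NAC list 0, 2 and 3. The test called 1995 genes, 1098 higher and 897 lower in Pinot noir.

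At day 42, MYB14 (VIT_07s0005g03340) was at 17.4 ± 4.27 RPKM in Pinot noir and 0.78 ± 0.38 in Cabernet Sauvignon (SD, n = 9; 3.37), and MYB15 (VIT_05s0049g01020) at 132 ± 33.2 against 28.7 ± 10.7 RPKM (2.21). 3AT (VIT_03s0017g00870) was at 2.98 ± 0.52 against 20.1 ± 6.70 RPKM (-2.35, SE 0.14), and UFGT (VIT_16s0039g02230) at 78.5 ± 8.11 against 34.7 ± 8.96 RPKM (1.19, SE 0.22). The proanthocyanidin regulator MYBPA1 (VIT_15s0046g00170) was higher by 2.47 (21.0 against 3.38 RPKM) and ANR (VIT_00s0361g00040) by 1.47 (0.57 with a pseudocount of 5). CHS1 (VIT_14s0068g00930) was higher by 1.77, CHI (VIT_13s0067g03820) by 1.55 (232 against 78.3 RPKM) and CHS3 (VIT_05s0136g00260) by 1.44 (964 against 357 RPKM). NAC26 (VIT_01s0026g02710) was higher by 1.13 (0.63 re-anchored), NAC13 (VIT_02s0012g01040) differed by -1.11 and NAC11 (VIT_14s0108g01070) by -1.10, or by -0.93 in seasons with both cultivars in the same batch. Genes known by ID alone differed by up to 8.10 for VIT_06s0004g02010 and 7.37 for VIT_05s0077g01150, and down to -5.41 for VIT_12s0035g00730 and -4.93 for VIT_19s0085g00920. Both stilbene genes were higher (camera adjusted p = 0.00773; adjusted p = 0.108 with an estimated correlation), and the other lists had, as higher, lower and not passed, 1, 1 and 7 (anthocyanin), 3, 0 and 8 (flavonoid core), 2, 0 and 6 (proanthocyanidin) and 1, 2 and 2 (NAC). The test called 2279 genes, 1404 higher and 875 lower, and the list counts at the 3 stages were the same adjusted over the list alone.

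The seasons were compared at days 21 and 42 in both cultivars (12 libraries per side). Ripening stage at these days was not matched. At day 21 of 2014 mean sugar content was 15.2 and 14.4 in Cabernet Sauvignon and Pinot noir. In 2012 and 2013 it was 16.0 to 17.8. At day 42 it was 20.9 and 23.9 in 2014, against 19.5 and 26.5 in 2012 and 23.8 and 22.9 in 2013. Season and ripening stage were therefore not separated. MYB15 (VIT_05s0049g01020) was higher in 2013 than in 2012 by 1.06 (SE 0.14), and by 0.99 with both scalings, under the size threshold. MYBA1 (VIT_02s0033g00410) was lower in 2014 than in 2012, at 18.4 ± 8.50 against 39.0 ± 14.0 RPKM (SD, n = 12; log2 difference -1.10, SE 0.20; -0.91, under the size threshold, without replicate 3). Within 1 batch, as set out below, MYBA1 differed by -0.72 between 2013 and 2012 and by 0.36 between 2014 and 2013, both under the size threshold. No list gene of the 35 passed between 2014 and 2013, and none besides these 2 in the other 2 comparisons, with the same counts adjusted over the list alone. No list passed camera between seasons. The list of flavonoid core genes had a median difference of 0.19 from 2012 to 2013 where camera pointed down (adjusted p = 0.918). The tests called 170 genes between 2013 and 2012 (39 higher and 131 lower), 409 between 2014 and 2012 (32 and 377) and 337 between 2014 and 2013 (64 and 273). Between 2013 and 2012, and between 2014 and 2013, limma called 0 genes with the 4 cultivar-day means as replicates, with 3478 and 3196 at an unadjusted p under 0.05.

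The libraries fell into a pair of sets by 91 genes with a 5% quantile over the 2012 libraries more than 1 (log2 scale) above the 95% quantile over the 2014 libraries. Of the 75 libraries of 2013, 62 lay with 2012 and 13 with 2014, and these 13 were the last 4 time points of Cabernet Sauvignon and 1 replicate at day -13. These sets are called batches here. Within 1 batch the difference between 2014 and 2013 could be had from Cabernet Sauvignon at day 42 alone, with 291 genes (206 higher and 85 lower), a split turned against the pooled one. Within 1 batch 2013 differed from 2012 in 152 genes (46 higher and 106 lower), over 3 of the 4 cultivar-days, without Cabernet Sauvignon at day 42. No batch held both 2012 and 2014, so these seasons could not be compared within 1 batch. Without the 91 genes, 318 genes differed between 2014 and 2012, 32 higher and 286 lower. Of these 286, 5.59% were lower by at least 1 in 2013 than in 2012 within 1 batch (the same 3 cultivar-days), against 0.574% of all genes. In the 1 replicate at day -13, 61.9% were lower than in the other 2 of that sampling, against 2.71% of all genes.

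**Figure D4:**
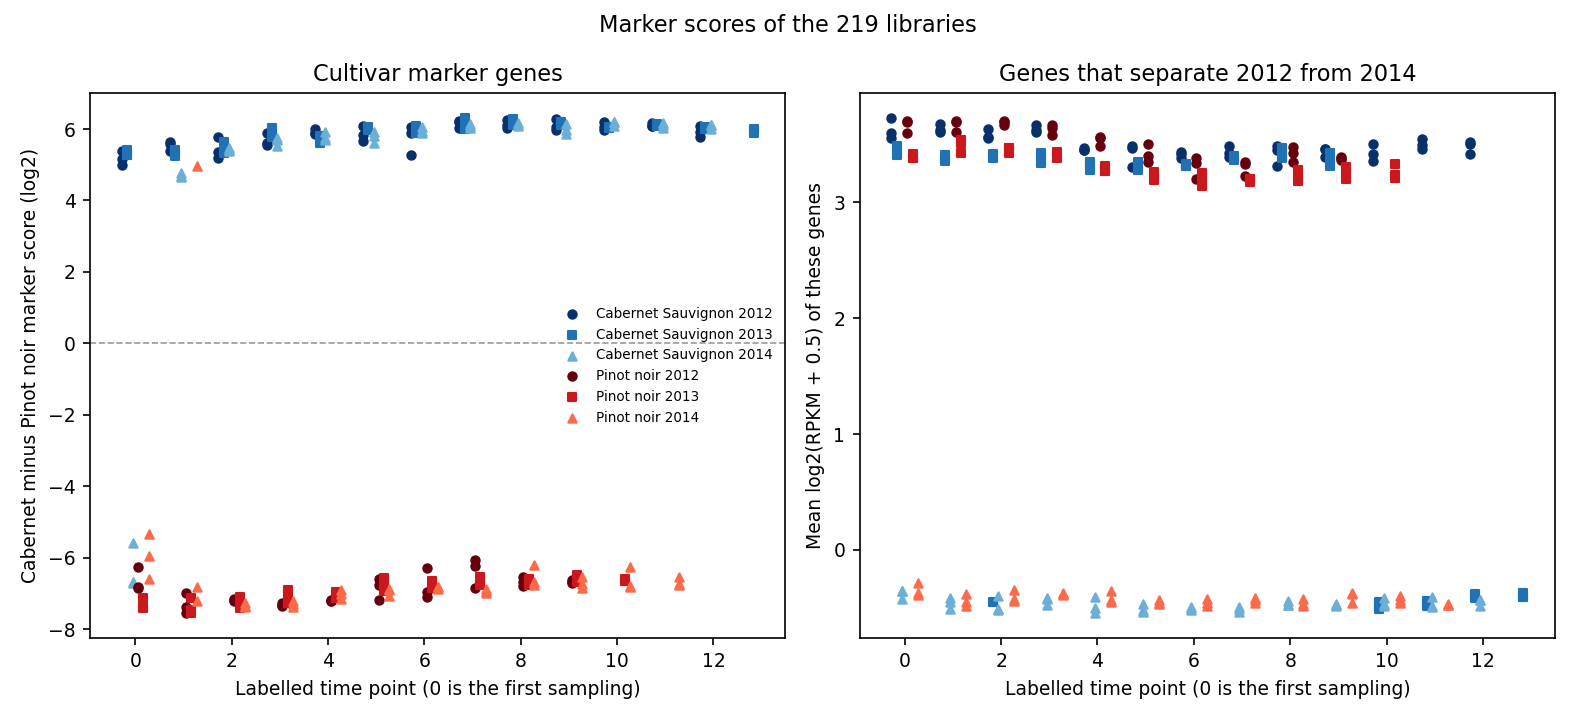
Marker scores of all libraries against the labelled time point, by cultivar and season, with the score of 22 Cabernet Sauvignon minus 26 Pinot noir marker genes (left) and the mean of 91 genes that separate 2012 from 2014 (right), both on a log2 scale. On the left 4 libraries of 2014 lie with the other cultivar, and on the right 13 libraries of 2013 lie with those of 2014.

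Interaction terms asked whether steps differed between cultivars (Pinot noir minus Cabernet Sauvignon, 9 libraries per side and cultivar). The steps need not span the same ripening stages in both cultivars. At the onset window mean sugar content was 1.55, 2.00 and 0.56 in Cabernet Sauvignon of 2012 to 2014. In Pinot noir it was 3.58, 2.97 and 1.34. From before onset to day 21, MYB14 (VIT_07s0005g03340) had log2 changes of 1.02 in Pinot noir and -1.68 in Cabernet Sauvignon (difference 2.70, SE 0.28). 3AT (VIT_03s0017g00870) had changes of 1.79 and 3.78 (difference -1.99, SE 0.19), or with a difference of -0.65 at a pseudocount of 0.1, under the threshold. NAC11 (VIT_14s0108g01070) had changes of 2.14 and 4.09 (difference -1.95, SE 0.18) and LDOX (VIT_02s0025g04720) of 0.85 and 2.61 (difference -1.76, SE 0.21). For VIT_16s0050g00900 the changes were -0.80 and -2.35 (difference 1.55; 0.72 with a pseudocount of 5) and for F3H1 (VIT_04s0023g03370) 0.85 and 2.16 (difference -1.32, SE 0.25; -0.10 with 2014 re-anchored by sugar). For AOMT (VIT_01s0010g03510) they were 5.27 and 4.00 (difference 1.28, SE 0.36), and with a pseudocount of 5 the difference was 0.35 (adjusted p = 0.24), under the threshold. The anthocyanin list had differences of 2 higher, 2 lower and 5 not passed, the flavonoid core list 0, 2 and 9, the proanthocyanidin list 1, 1 and 6, the stilbene list 1, 0 and 1 (camera adjusted p = 0.0354; adjusted p = 0.185 with an estimated correlation) and the NAC list 1, 1 and 3. In all 1842 genes differed, 1114 higher and 728 lower.

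At the onset step CHS3 (VIT_05s0136g00260) had changes of -1.04 in Pinot noir and 1.02 in Cabernet Sauvignon (difference -2.06, SE 0.36). The changes were -0.95 and 0.75 for F3H1 (VIT_04s0023g03370; difference -1.70; -0.45 re-anchored), and CHS2 (VIT_14s0068g00920) had -0.40 and 0.91 (difference -1.31; -0.32 re-anchored) and ANR (VIT_00s0361g00040) had -1.38 and -0.26 (difference -1.12; 0.38, the other direction, re-anchored). The flavonoid core list had 3 lower and 8 not passed (camera adjusted p = 4.51e-05; adjusted p = 0.185 with an estimated correlation), the proanthocyanidin list 1 lower and 7 not passed, and the others none past the threshold. At the veraison step ANR (VIT_00s0361g00040) had changes of -0.54 and -1.79 (difference 1.26; 0.34 re-anchored) and 3AT (VIT_03s0017g00870) of 1.00 and 2.09 (difference -1.09; -0.77 re-anchored and -0.22 with a pseudocount of 0.1; held in 13 of 21 alternatives). CHS3 (VIT_05s0136g00260) had changes of 2.93 and 1.83 (difference 1.10; -0.024 re-anchored), and this difference did not pass in a fit of the compared libraries alone. The anthocyanin list had 1 lower and 8 not passed, the flavonoid core list 1 higher and 10 not passed and the proanthocyanidin list 1 higher and 7 not passed. The onset step differed in 225 genes (100 higher and 125 lower) and the veraison step in 332 (241 and 91). Of 10 splits of the cultivar-seasons, the real one included, 7 gave as many genes for the onset step (highest other 969). For the veraison step 2 did (highest other 405), so these counts do not single out cultivar. The list counts of the 3 interactions were the same adjusted over the list alone. With season means as replicates limma called 0 genes for the onset and veraison differences, with 431 and 1485 at an unadjusted p under 0.05.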

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

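The tests of the 4 libraries that carried the other cultivar's markers and of the 91 genes that separate the batches were chosen only after the result was seen, as were the tests of parts of the other 286 genes and the comparison of 2013 with 2012 within a batch.

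The 3 libraries of Cabernet Sauvignon at day -23 of 2014 and replicate 2 of Pinot noir at day -14 of 2014 carried the marker genes of the other cultivar. The 22 Cabernet Sauvignon and 26 Pinot noir markers were chosen on later time points of 2012 and 2013, and the scores of these libraries (-6.70, -6.67, -5.58 and 4.98) lay inside the range of the other cultivar's side in 4 of 4 cases (-7.55 to -5.34 over 98 Pinot noir libraries and 4.67 to 6.30 over 117 Cabernet Sauvignon libraries). A mixture with at least 5% of the label's own cultivar is argued against, since the label's own markers reached at most 0.915% of their usual median RPKM. A smaller share stays open in replicate 3 of Cabernet Sauvignon, where 18.2% of the Cabernet Sauvignon markers were detected against 0.0% in replicates 1 and 2, as in the highest of the 98 Pinot noir libraries. Markers silent in young berries are argued against, since 0 of 36 libraries from the first 3 time points of 2012 and 2013 lay on the wrong side. Mislabelled libraries may therefore be the source, as a hypothesis, but 3 libraries against 1 do not form matching partners of a swap between these groups. Apart from markers silent in young berries, no biological explanation was tested.

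The onset step differed between 2014 and the mean of 2012 and 2013 in 1064 genes by labelled day and the veraison step in 399, each by an interaction term. A library of the other cultivar before onset is argued against as the cause, since 1037 genes differed at the onset step without it. A labelled day 0 that came earlier in ripening in 2014 could account for part: with 2014 re-anchored by sugar the onset count was 581, which is neither under 50% of the labelled count nor as large as it, and the veraison count was 118. Re-anchoring moved the ripening count from 1108 to 915 and the post-veraison count from 376 to 41, but the late count rose from 78 to 177. Gaps between 2014 and the other seasons were also taken along a separate first principal component. It was computed from the libraries of 2012 and 2013 alone, and those of 2014 were projected onto it. At the onset and veraison windows the gaps were -24.8 and -34.0 in Cabernet Sauvignon and -27.4 and -27.1 in Pinot noir by labelled day. Re-anchored they were 17.2, 21.5, 20.6 and 5.53, so a shift of 1 time point overshot at these windows. Before onset the gap went from 2.73 to 15.7 in Cabernet Sauvignon and from 6.84 to 26.3 in Pinot noir. The re-anchored onset step of 2014 therefore started further along this component. Over all windows the mean absolute gap went from 14.2 to 14.6 in Cabernet Sauvignon and from 17.7 to 10.2 in Pinot noir. Timing and a season effect beyond timing cannot be told apart, because weekly samplings leave no closer match.

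A batch that crosses the seasons was weighed for the genes lower in 2014 than in 2012. For the 91 genes with a gap between the 2012 and 2014 libraries (5% quantile of 2012 over 95% quantile of 2014), the growing season is argued against, since 62 of the 75 libraries of 2013 lay with 2012 and 13 with 2014, among them a single replicate at day -13 of Cabernet Sauvignon. Of these genes 38 (41.8%) had IDs of the unplaced 00 series, against 8.12% of the genes tested (Fisher's exact test, p = 2.13e-18), and a processing or library batch may be the source. The other 286 genes called lower shared it in part, as 68.9% were lower by at least 1 on the log2 scale at day 43 (other batch) than at day 36 in Cabernet Sauvignon of 2013, against 2.80% from day 29 to day 36. In the 1 replicate of day -13 in the other batch 61.9% were lower than in replicates 2 and 3, against 2.71% of all genes. Within 1 batch 1.75% of the 286 were lower in 2014 than in 2013 (Cabernet Sauvignon at day 42 alone), against 0.635% of all genes. In 2013 5.59% were lower than in 2012 (3 of the 4 cultivar-days, without Cabernet Sauvignon at day 42), against 0.574% of all genes. The medians were -0.0061 and -0.09, against -1.39 between 2014 and 2012. These values argue against the season as the cause of the set as a whole, for the cultivar-days that they cover. Between 2014 and 2013, Pinot noir and day 21 were not covered. The season is argued against most for the 197 genes also lower at day 43, of which 75.6% were lower in that replicate. For the 89 genes not lower by 1 at day 43 batch and season cannot be told apart, since no batch holds both 2012 and 2014. Of these 89 genes 15.7% were lower in 2013 than in 2012 within 1 batch, against 0.574% of all genes. The genes were chosen with the same libraries of 2012, which favours lower values in 2013. In the 1 replicate of day -13 in the other batch 31.5% of them were lower, against 2.71% of all genes.

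The other results came from interaction terms, which tested the cultivar difference of a step itself. The ripening difference was past the threshold in 1842 genes, and 10 splits of the 6 cultivar-seasons are too few for a share under 0.05 (real value 1842, highest other 1182; 1 split as large, the real one included). The onset difference was past it in 225 genes, and 7 of the 10 splits gave as many, with a highest other of 969, which points to a structure of the samples other than cultivar. The veraison difference was past it in 332 genes, and 2 of the 10 splits gave as many (highest other 405), again too few for a share under 0.05. For ripening the named differences (Pinot noir minus Cabernet Sauvignon) were 2.70 for MYB14 (VIT_07s0005g03340), 1.55 for VIT_16s0050g00900, 1.28 for AOMT (VIT_01s0010g03510), 1.18 for NAC26 (VIT_01s0026g02710) and 1.08 for LAR1 (VIT_01s0011g02960). In the other direction they were -1.99 for 3AT (VIT_03s0017g00870), -1.95 for NAC11 (VIT_14s0108g01070), -1.76 for LDOX (VIT_02s0025g04720), -1.32 for F3H1 (VIT_04s0023g03370), -1.15 for LAR2 (VIT_17s0000g04150) and -1.10 for CHS3 (VIT_05s0136g00260). Several of these depend on the processing. With 2014 re-anchored by sugar the difference was -0.099 for LAR2 (held in 15 of 21 alternatives), -0.35 for CHS3 (13 of 21) and -0.097 for F3H1 (18 of 21). With a pseudocount of 5 it was 0.57 for LAR1 (13 of 20), 0.35 for AOMT (17 of 21) and 0.72 for VIT_16s0050g00900 (18 of 20), and with a pseudocount of 0.1 it was -0.65 for 3AT (20 of 21). For NAC26 it was 0.95 without 2012 (19 of 21). For the onset step they were -2.06 for CHS3, -1.70 for F3H1, -1.31 for CHS2 (VIT_14s0068g00920) and -1.12 for ANR (VIT_00s0361g00040), and for the veraison step 1.26 for ANR, 1.10 for CHS3 and -1.09 for 3AT. Re-anchored, the onset differences of F3H1, CHS2 and ANR were -0.45, -0.32 and 0.38 and the veraison differences of ANR and CHS3 0.34 and -0.024, while that of 3AT was -0.22 with a pseudocount of 0.1.

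Other splits of the compared libraries were drawn within cultivar-seasons, seasons or cultivar-days, with counts from fits without the robust option. For each of these comparisons 1 of 100 splits, the real one, gave as many genes. The other splits put libraries of both compared samplings on each side, which widens the spread within a side. They therefore show only that the compared libraries were not interchangeable. The splits do not cover the spread between seasons or cultivar-seasons. With stratum means as replicates limma called 0 genes for the onset step, the cultivars before onset, 2013 against 2012 and 2014 against 2013, with 5821, 4930, 3478 and 3196 at an unadjusted p under 0.05. It called 5112 for ripening, 867, 162 and 861 for the veraison, post-veraison and late steps, and 303 for 2014 against 2012. For the cultivars it called 1902 at day 21 and 2053 at day 42. The real and highest other counts were 5262 and 1110 for ripening, 621 and 30 for the onset step, 893 and 5 for the veraison step, 224 and 18 for the post-veraison step and 913 and 81 for the late step. They were 1126 and 605 for the cultivars before onset, 1994 and 5 at day 21 and 2267 and 813 at day 42. Between seasons they were 165 and 39 (2013 and 2012), 410 and 24 (2014 and 2012) and 336 and 182 (2014 and 2013). These splits do not separate season from batch or from ripening stage. For the largest successive steps 10 splits are too few for a share under 0.05, with real and highest other counts in Cabernet Sauvignon of 2392 and 2 (2012), 1670 and 4 (2013) and 2241 and 1 (2014), and in Pinot noir of 2733 and 6, 1433 and 3, and 826 and 2.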

How the results depend on the processing

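The alternatives without the 4 libraries, within batches, with both together and without the batch genes were chosen only after the results were seen, and a check of the always-named genes outside the named set was added after a first pass.

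The read depth is unknown, so the precision of low values rests on the spread between replicates. Under no filter, TMM scaling and the replicate block, all 20 counts stayed within 1.5 times their value, as did all 14 in the fit of the compared libraries only. With the replicate block the counts were 5262 for ripening, 1160 for the cultivars before onset, 2021 at day 21 and 2285 at day 42. Deviations of replicates with the same number in the windows compared correlated above 0.1 in 19 of 90 pairs (median 0.0096). In 35 the library correlated best with its own number. Whether the numbers mark the vine-row blocks cannot be read from this, and libraries were not paired in the main fit. Of 151 named values past the threshold, 149 were past it with the block, 145 with quantile scaling, 145 with TMM scaling and 116 with a pseudocount of 5. Without the 4 libraries 151 were, and in same-batch comparisons 142 were, with 4 under the threshold and the 5 of 2014 against 2012 without a value. No value in the named set (pairs outside it are given below) reversed under the other alternatives, except with 2014 re-anchored by sugar the onset difference of ANR (VIT_00s0361g00040) at 0.38 and the veraison difference of CHS3 (VIT_05s0136g00260) at -0.024, and with 2013 left out the veraison difference of AOMT (VIT_01s0010g03510) at -0.36. The cause was not tested for these or for the counts given next unless a cause is named.

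A pseudocount of 0.1 widens and a pseudocount of 5 narrows changes of low genes by construction. With 0.1 the counts were 1284 for the onset, 1914 for the veraison, 775 for the post-veraison and 2024 for the late step, and 2292, 3774 and 4143 for the cultivars at the 3 stages. They were 624 (2013 and 2012), 824 (2014 and 2012) and 820 (2014 and 2013) for the seasons and 3229, 510 and 654 for the cultivar differences of ripening, onset and veraison. The largest successive steps had 3973, 2919 and 3589 genes in Cabernet Sauvignon of 2012 to 2014 and 2752 and 1852 in Pinot noir of 2013 and 2014. With 5 the counts were 2976 for ripening, 279, 394, 79 and 389 for the 4 steps, 444, 850 and 1022 for the cultivars, 57, 180 and 117 for the seasons, and 840, 71 and 135 for the cultivar differences. The successive steps then had 1260, 987 and 994 genes in Cabernet Sauvignon and 1606, 681 and 535 in Pinot noir.

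With a mean RPKM of at least 5, which tests fewer genes, ripening called 3415, the cultivars 516, 1237 and 1437, 2014 against 2012 248, the ripening and onset differences 1078 and 133, and the successive steps of Cabernet Sauvignon of 2013 and 2014 and Pinot noir of 2012 1231, 1228 and 1797. With quantile scaling the largest step of Cabernet Sauvignon of 2012 moved to day -37 to -28 (2241). With TMM scaling it stayed at day -9 to 0, where the split of higher and lower moved to 965 and 1201 from 702 and 1812. The split moved in Pinot noir of 2012 to 1167 and 1485 (quantile), of 2013 to 587 and 689 (quantile) and 598 and 740 (TMM), and of 2014 to 502 and 510 (quantile). The treat test, whose null allows changes up to 0.5, called 8756 for ripening, 1223, 1844, 462 and 1796 for the 4 steps, 3449 for the cultivars at day 42, and 41 and 77 for the onset and veraison differences.

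With 2014 re-anchored the onset step called 988. Leaving out 2012 gave 364 for the onset step and 138 for its cultivar difference, leaving out 2013 gave 406 for the post-veraison step and 726 for the onset difference, and leaving out 2014 gave 1202 for the onset step and 428 for its difference. With stratum means as replicates limma called 0 genes for the onset step, the cultivars before onset, 2013 against 2012, 2014 against 2013 and the onset and veraison differences. At an unadjusted p under 0.05 these had 5821, 4930, 3478, 3196, 431 and 1485 genes. The ripening difference had 541, and 90 of the named values passed, where fewer samples are compared. Ripening kept 5112 genes, the veraison, post-veraison and late steps 867, 162 and 861, and 2014 against 2012 303. The cultivars kept 1902 at day 21 and 2053 at day 42. The estimated correlation left 4 of 14 list tests past the threshold. Without the 4 libraries the largest step of Cabernet Sauvignon of 2014 was from day 0 to day 8 (1790).

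Leaving out each replicate number in turn gave 153 to 407 genes for the post-veraison step, 197 to 404 for the veraison difference, 2528 to 2919 for the largest step of Cabernet Sauvignon of 2012 (2659 at another step, day -37 to -28), 1579 to 2338 for 2013 (1855 at day -6 to 0) and 888 to 1373 for Pinot noir of 2014 (1200 at day -20 to -14). Same-batch comparisons gave no value for 2014 against 2012.

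The 6 always-named genes had 39 gene and comparison pairs outside the named set. These pairs were set aside after a first pass because their adjusted p was not under 0.05 in the main fit. Of their 770 values under the alternatives 59 had the opposite sign, and 4 of these passed, all with 2013 left out. The onset difference was 1.31 for UFGT (VIT_16s0039g02230; -0.11 with all seasons) and 1.91 for GST4 (VIT_04s0079g00690; -0.49), and the veraison difference was -1.12 for MYBA1 (VIT_02s0033g00410; 0.03) and -1.24 for MYBA2 (VIT_02s0033g00390; 0.14).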

Other observations

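The test of sugar content against component scores, and the overlaps and last samplings, were chosen only after the result was seen.

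Of 759 genes higher at day 0 than before onset, 175 were lower at day 42 than at day 0, and of 1922 genes lower at day 0, 54 were higher at day 42. None of these was a list gene (0 in both directions, limma, same thresholds). Both comparisons share the day 0 libraries, which favours opposite signs, and a return to the level before onset was not tested. The genes that separated day 21 from before onset were in part called earlier: at the onset window 21.7% of the higher and 7.39% of the lower genes were past the threshold against before onset, at day 0 52.0% and 44.9%, and at day 7 to 11 68.0% and 73.7%. Those shares compare windows with the same before-onset libraries. With these libraries split between the comparisons they were 20.4% and 6.04%, 51.8% and 42.7%, and 66.9% and 70.9%. Cultivar differences at all 3 stages were called for 226 genes higher and 193 genes lower in Pinot noir, and 44 genes called both before onset and at day 42 had opposite signs.

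At the last sampling of each season (n = 3 per cultivar and season), MYB14 (VIT_07s0005g03340) had mean RPKM of 16.6 to 25.0 in Pinot noir (day 50 to 53) and 1.12 to 3.54 in Cabernet Sauvignon (day 63 to 80). MYB15 (VIT_05s0049g01020) had 127 to 160 against 29.7 to 39.2, whereas NAC11 (VIT_14s0108g01070) had 24.7 to 42.5 against 94.0 to 126 and FLS (VIT_18s0001g03470) 1.31 to 2.23 against 4.83 to 19.1. These days differ between cultivars, and no test was made.

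A hypothesis was that replicates of a sampling may differ in ripening stage, so that their spread holds a part of the ripening programme. Deviations of replicates from their group mean in sugar content and in the first principal component correlated over 73 groups of 3 libraries (Pearson r = 0.406, permutation p = 3e-05, adjusted p = 0.00027; Spearman rho = 0.345, permutation p = 4e-05, adjusted p = 0.00036; 9 relations computed, replicates permuted within groups). Without the 2 libraries farthest in sugar deviation r was 0.362. Within batches r was 0.417 (129 libraries; permutation p = 9e-05; rho 0.405) and 0.392 (87 libraries; permutation p = 0.0324; rho 0.238, permutation p = 0.0666), and in the latter it fell to 0.227 without the 2 farthest. The relation did not hold in every cultivar-season: r was 0.668, -0.0272 and -0.111 in Cabernet Sauvignon of 2012 to 2014 and 0.491, 0.525 and 0.636 in Pinot noir. The hypothesis was formed and tested on the same data.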
